A study of Mus musculus with 8 samples.

How the data were processed

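RNA of double-positive thymocytes, the immature T cells that carry both CD4 and CD8, was measured on 8 one-colour Affymetrix mouse arrays. Each array held biotin-labelled cRNA from 1 mouse. All mice lacked the T-cell receptor alpha gene, and per the labels' protocols the cells were enriched on magnetic columns with an antibody against CD4. Groups were taken from the titles and the genotype field, which put 4 mice in the c-Myb sufficient (control) group and 4 in the c-Myb deficient (mutant) group. The source names run the other way: they give the controls the floxed homozygous Myb genotype with Cd4-Cre and give the mutants a floxed and a wild-type allele. The groups are therefore called by their label throughout, and each difference is the arrays labelled deficient minus the arrays labelled sufficient. The labels call the arrays biological replicates, so the spread between arrays is the spread between mice.

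The deposited table holds one linear intensity (signal) per probe set and array, made with GCOS, the Affymetrix operating software, per the submitters' processing notes. Its version and settings are not given in the sources used here. The deposited intensities ran from 0.1 upward, and the 2% trimmed mean was 250.0 on each of the 8 arrays, so each array had been scaled to a common level. Such scaling removes any difference in total RNA per cell. Detection calls were not used here, and no scan date or chip batch was at hand, so batches were not tested. For arrays, the number of arrays limits the precision, and signals near the background limit it further.

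From there the intensities were used as deposited and converted to log2(signal + 16). A fold change on this scale understates the change of dim genes, and its size depends on the pseudocount where a group is dim. Where a gene was below the dim limit on every array of 1 group, its fold is given as a lower bound, the mean of the bright group against that limit on the log2 scale. Of 45101 probe sets, 64 controls were left out. The platform annotation gave 34945 probe sets 1 gene symbol, 932 several and 9160 none. Gene identifiers of 34741 probe sets were found in the RefSeq gene table of GRCm38.p6, which served for current symbols only. No coordinates are given, since the annotation of the array names no build. Genes without a 1-symbol probe set in this annotation, some members of the lists among them, are not analysed here. A probe set was kept when its signal passed the median of the whole table, 33.8, on at least 4 of the 8 arrays. Each gene was represented by its 1-symbol probe set with the highest mean log2 signal, which left 9951 genes.

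Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend, two-sided), with Benjamini-Hochberg adjustment over the 9951 genes and a threshold of 0.05 on the adjusted p. All adjusted p-values come from this model unless another test is named. For the probe sets of the targeted gene, a two-sided exact permutation test over the 70 labellings was added. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. The groups, the test, the alternatives, the 25 gene lists and the rule for named genes were fixed before the data were examined. The rule names Myb and preset genes of thymocyte biology, the 6 largest rises and 6 largest falls among changed genes whose groups of arrays do not overlap, and up to 2 changed members of each list with the largest change. Where a list had no changed member, its brightest tested member is named.

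The lists were tested against all other genes with limma's camera at a preset correlation of 0.01, adjusted over the 22 lists with at least 3 tested members. Camera with an estimated correlation and fry were the alternatives. The lists covered apoptosis, p53 targets, thymocyte stages, T-cell receptor signalling, reported c-Myb targets, proliferation, metabolism, cytokine receptors, E proteins, interferon, glucocorticoid and immediate early responses, sex-linked genes and markers of other cell types. Other alternatives changed the normalization, pseudocount, dim filter, probe set choice, variance model, array weights and threshold, added the replicate number as a block, or left out each array in turn. A fit with the Xist level as a covariate was added after the data had been seen. The level entered as a class, high or low, cut at a signal of 1000 on the brightest Xist probe set. That fit assumes that the lone sufficient array with high Xist varies like the others. The method was tested on simulated data for the comparison of deficient with sufficient arrays over 9951 genes. Of 50 genes changed at each size, 6% were recovered at 1.25-fold, 52% at 1.5-fold, 72% at 2-fold and 100% at 4-fold. In that run 6 of 121 calls were false, and with no change simulated 0 genes and 0 lists were called. The simulated genes varied independently of one another, so the 0 lists do not check camera where members of a list vary together.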

Results

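The series asked how loss of c-Myb, a transcription factor of immature blood cells, alters double-positive thymocytes before positive selection. Cells came from 4 mice labelled c-Myb sufficient and 4 labelled c-Myb deficient, and each mouse had its own array. Array medians lay between 30 and 37.9 signal units. Log2 signals of arrays of the same group correlated across probe sets at 0.974 to 0.984, and those of different groups at 0.964 to 0.979. No pair of arrays was a copy of another, since at most 271 of 45101 values were identical. Signals are given as mean ± SD over 4 mice per group, and log2 differences with their standard error (SE).

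Myb transcripts were abundant in both groups and were not lower on the arrays labelled deficient. The brightest Myb probe set, 1421317_x_at, read 9362 ± 1151 on sufficient and 11291 ± 543 (SD, n = 4) on deficient arrays, a log2 difference of 0.28 ± 0.08 (SE) with an adjusted p of 0.0619 in limma. All 4 deficient arrays lay above the 4 sufficient ones, and the two-sided exact permutation p was 0.0286, the smallest that 70 labellings can give. Probe set 1422734_a_at read 4518 ± 460 and 5777 ± 428, with the same exact p of 0.0286 and an adjusted p of 0.0327 over probe sets. Probe set 1450194_a_at differed by 0.04, with an exact p of 0.714. Where these probes lie relative to the floxed part of Myb is not given in the sources used here, and probes outside a deleted part do not check the genotype. The levels therefore do not settle the conflict between the genotype field and the source names, and every direction below is that of the arrays as labelled.

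**Figure D1:**
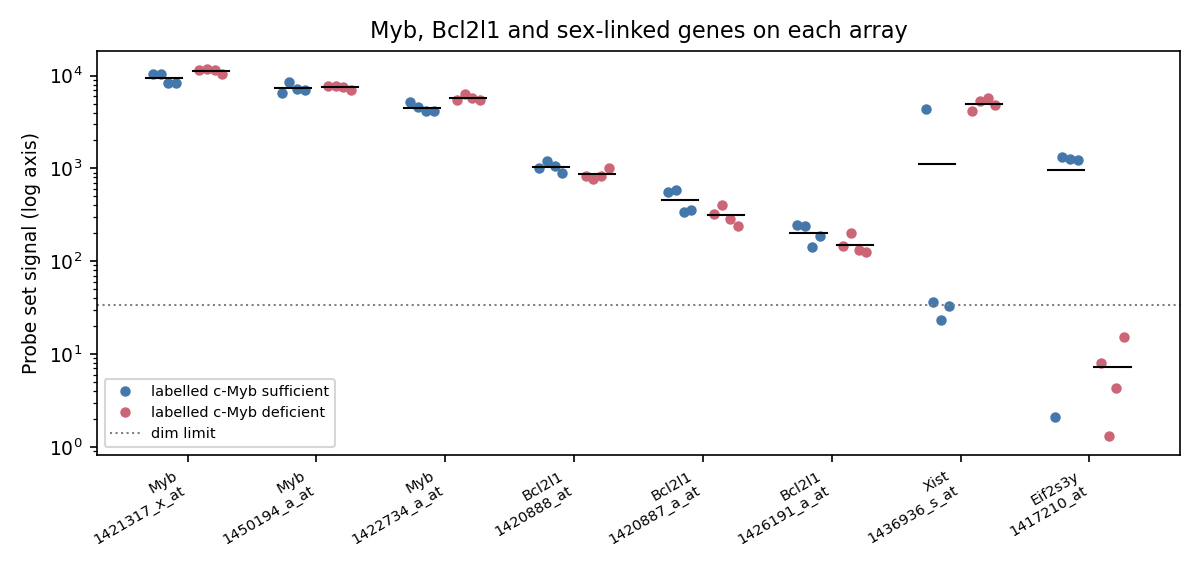
Probe set signals on a log axis for Myb, Bcl2l1 and the sex-linked genes Xist and Eif2s3y. Each point is 1 array (4 labelled sufficient in blue, 4 labelled deficient in red), black bars are group means, and the dotted line is the dim limit of 33.8. Sufficient replicate 1 reads 4358.5 for Xist, near the deficient arrays, while the other sufficient arrays read 23.4 to 36.7.

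On the arrays labelled deficient, Il18r1, a subunit of the interleukin-18 receptor, rose from 30.2 ± 25.6 to 3576 ± 1378 (SD, n = 4 each). The transcription factors Fosl2 and Maf rose from below or near the dim limit to 902 ± 189 and 1839 ± 837. Ccr7, a chemokine receptor of mature thymocytes, rose from 60.1 ± 43.1 to 824 ± 87.0, and Cxcr4, a chemokine receptor of double-positive cells, fell from 4339 ± 153 to 1316 ± 448. In all, 992 of 9951 genes (9.97%) changed, 586 higher and 406 lower. At least 2-fold changes by the fitted difference were seen in 153 of the higher and 60 of the lower genes. Of these, 18 and 3 were below the dim limit on every array of 1 group, so that their fold is a bound. That bound was under 2-fold for some of the 18 rises (1.516 for Btc) and for the 3 falls (1.51 to 1.798). Groups of arrays did not overlap for 17.0% of tested genes, against 2.86% by chance, and for 931 of the 992 changed genes. A further measured difference went with the groups: Xist was high in all 4 deficient mice (4129 to 5736) and in sufficient replicate 1, but low in sufficient replicates 2, 3 and 4. With the Xist level in the model, chosen after the data were seen, the deficient arrays were compared with sufficient replicate 1 alone. All 992 differences kept their sign at a median of 0.89 of their size, and the median SE went from 0.128 to 0.206. For the 931 genes whose groups do not overlap the sign could not change, so the kept sign does not test an effect of sex. The count of changed genes was 494 without sufficient replicate 3, and 605, 515 and 579 without deficient replicates 1, 2 and 3. Array weights raised the count to 1742, and leaving out deficient replicate 4, whose 18S rRNA control read 7143 against 676 to 1459 elsewhere, gave 1198.

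Among the 6 largest rises, Il18r1 (probe set 1421628_at) differed by a log2 of 6.39 ± 0.42 (SE, adjusted p = 1.83e-05). Its sufficient mean lay below the dim limit, and the difference was 7.48 with a pseudocount of 1 and 5.225 with 64. Fosl2 (1437247_at), a member of the AP-1 family, was below the dim limit on all 4 sufficient arrays and at least 26.25-fold higher on deficient ones (adjusted p = 7.63e-08). Its other probe set differed by 1.18. Maf (1456060_at) rose by 4.91 ± 0.25 (adjusted p = 2.61e-06), and its 4 other probe sets by 2.28 to 4.11. The scavenger receptor family gene 5830411N06Rik (1438536_at) rose by 4.80 ± 0.61 (adjusted p = 0.00101), with deficient mice ranging from 409.5 to 4801. Ccr7 (1423466_at) rose by 3.65 ± 0.34, and Card6 (1436395_at), which encodes a caspase recruitment domain protein, by 3.35 ± 0.19. The largest fall was that of Scn4b (1434008_at), a sodium channel beta subunit, from 686.4 ± 152 to 68.4 ± 31.5 (log2 -3.09 ± 0.23, adjusted p = 6.83e-05). Next came A930003A15Rik (1455203_at, -2.91), the retinal reductase gene Dhrs3 (1448390_a_at, -2.62), Dgkeos (1456919_at, -2.62), the metalloprotease gene Adam12 (1421172_at, -2.54) and Smoc1 (1448321_at, -2.48), which encodes a calcium-binding matrix protein. Of these 12 genes, Il18r1, Fosl2, Maf, Ccr7, Card6, Scn4b, A930003A15Rik and Adam12 were also called with the Xist level in the model, where the other 4 differed by 4.75 (5830411N06Rik), -2.54 (Dhrs3), -3.06 (Dgkeos) and -2.32 (Smoc1).

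**Figure D2:**
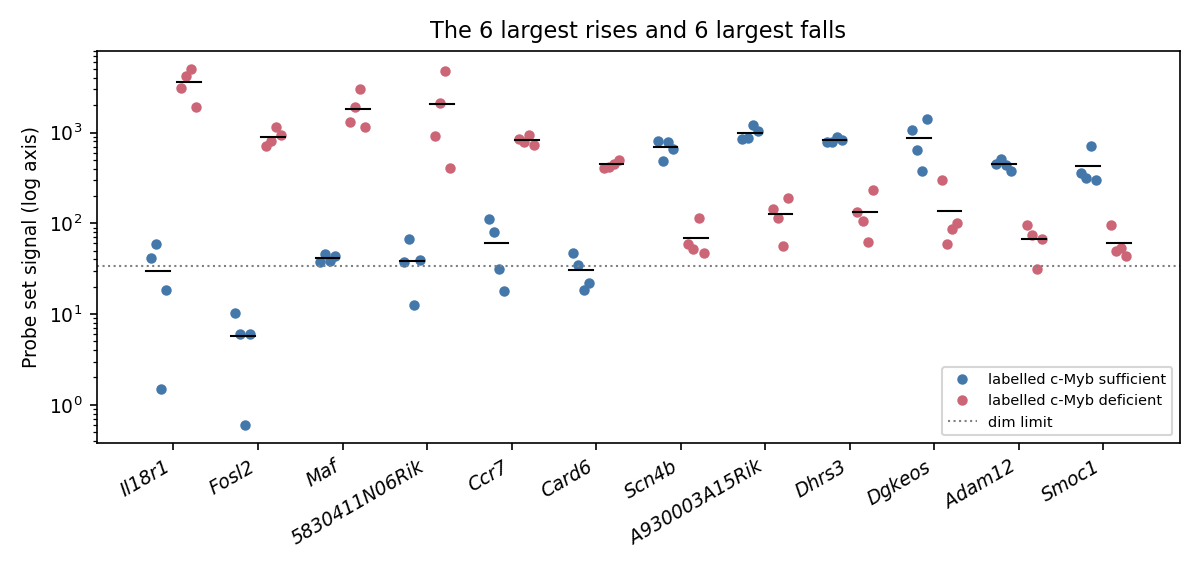
Signals on a log axis for the 6 largest rises and 6 largest falls. Each point is 1 array (blue, labelled sufficient; red, labelled deficient), black bars are group means and the dotted line is the dim limit of 33.8. For each gene all 4 arrays of one group lie on one side of all 4 arrays of the other, and 5830411N06Rik spreads from 409.5 to 4801 among deficient mice.

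Double-positive thymocyte genes were lower as a group. Of 26 tested members 10 fell and 1 rose, 15 did not pass, and adjusted over the list alone 12 fell and 2 rose. The median log2 difference was -0.17 (camera adjusted p = 4.59e-06, and adjusted p = 0.329 with an estimated correlation). Cxcr4 (1448710_at) fell by 1.78 ± 0.21 (adjusted p = 0.000582). Sh2d1a (1449393_at), the SAP adaptor of SLAM family receptors, fell from 3090 ± 354 to 1221 ± 322 (log2 -1.36), and the SLAM receptors Slamf1 and Slamf6 were lower too, as Slamf1 fell by 1.29 and Slamf6 fell by 1.15. Endou, Arpp21, Cd24a, Cd1d1, Rag2 and Dntt made up the other falls, and Plxnd1 rose by 0.40. Rag2, a recombinase gene, went from 4078 ± 122 to 3075 ± 232 (log2 -0.41 ± 0.07, adjusted p = 0.00557). Its partner Rag1 differed by -0.07 (adjusted p = 0.481), Cd4 by -0.08 (adjusted p = 0.731; -0.46 on its other probe set) and Cd8a by 0.04 (adjusted p = 0.769). With the Xist level in the model the list stayed past camera's threshold (adjusted p = 5.69e-07), with 2 members called lower.

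Mature single-positive thymocyte genes were higher as a group, with 7 of 18 tested members higher, 2 lower and 9 not past the test. Adjusted over the list alone, 10 were higher and 2 lower, with a median log2 difference of 0.57. Camera gave an adjusted p of 3.77e-05, and the list had adjusted p = 0.329 with an estimated correlation. Ccr7 and the integrin gene Itgb7 (112 ± 44.1 to 735 ± 280, log2 2.53) rose most, followed by Ccr4, Gimap4, Foxo1, Klf2 and S100a10. Ms4a6b fell by 0.87 and the interferon gamma receptor gene Ifngr1 fell by 0.58. With the Xist level in the model camera gave an adjusted p of 2.82e-05, and 1 member was called. Of 17 tested positive-selection response genes 4 rose and 4 fell (9 and 6 adjusted over the list alone), and the list as a whole did not pass (camera adjusted p = 0.497). The tetraspanin gene Cd53 rose by 2.88 ± 0.43 (1.38 on its other probe set) and the GTPase gene Gimap4 by 1.66 ± 0.24. Among double-negative thymocyte genes, which mark the stage before, 3 of 11 rose (Il2ra, Dtx1 and Notch1) and Gfi1 fell by 1.19. Adjusted over the list alone 4 rose and 1 fell, and the list did not pass camera (adjusted p = 0.189) but passed fry, upward (adjusted p = 0.0158). Il2ra, the interleukin-2 receptor alpha chain, went from 83.1 ± 76.3 to 753 ± 243 (log2 3.20). Dtx1, a Notch pathway gene, rose by 2.82 on its brightest probe set, while another differed by -0.08.

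Interferon response genes were higher, with 9 of 19 tested members higher, 1 lower and 9 not past the test. Adjusted over the list alone, 15 were higher and 1 lower. The median log2 difference was 0.78 (camera adjusted p = 1.74e-06, and adjusted p = 0.329 with an estimated correlation). Usp18 (1418191_at), a protease that removes ISG15, rose from 109 ± 32.3 to 494 ± 130 (log2 2.02 ± 0.21), and the antiviral gene Rsad2 (1436058_at) rose by 1.79 ± 0.42. Oas1a, Zbp1, Ifit3, Xaf1, Gbp2, Ifi35 and Ifi27 were the other rises, and Stat2 fell by 0.44. Ribosome biogenesis genes were slightly higher as a group: 4 of 22 passed, all higher (10 adjusted over the list alone, none lower), with a median of 0.28. Camera gave an adjusted p of 9.04e-05, and the list had adjusted p = 0.329 with an estimated correlation. Rrs1 rose by 0.40 and Mybbp1a, named for its binding to Myb, by 0.36, along with Npm1 and Wdr12. Of 13 glycolysis genes 4 rose and 1 fell (5 and 1 adjusted over the list alone), with a median of 0.22. Here camera's adjusted p was 0.0433, and adjusted p = 0.422 with an estimated correlation. The glucose transporter gene Slc2a3 rose by 0.96 and Pgam1 by 0.61, with Aldoa and Pkm also higher and Pfkp lower. Without probe sets prone to cross-hybridise, Slc2a3 differed by 0.67 and was not called (adjusted p = 0.249). Camera with the Xist level in the model gave adjusted p = 2.46e-06 for interferon genes, 1.34e-05 for ribosome biogenesis and 0.227 for glycolysis, and 0 members of these 3 lists were called in that fit. The glycolysis call also ended without sufficient replicates 2 and 3 (adjusted p = 0.0867 and 0.0818) and without deficient replicates 1 and 4 (0.0535 and 0.121).

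**Figure D3:**
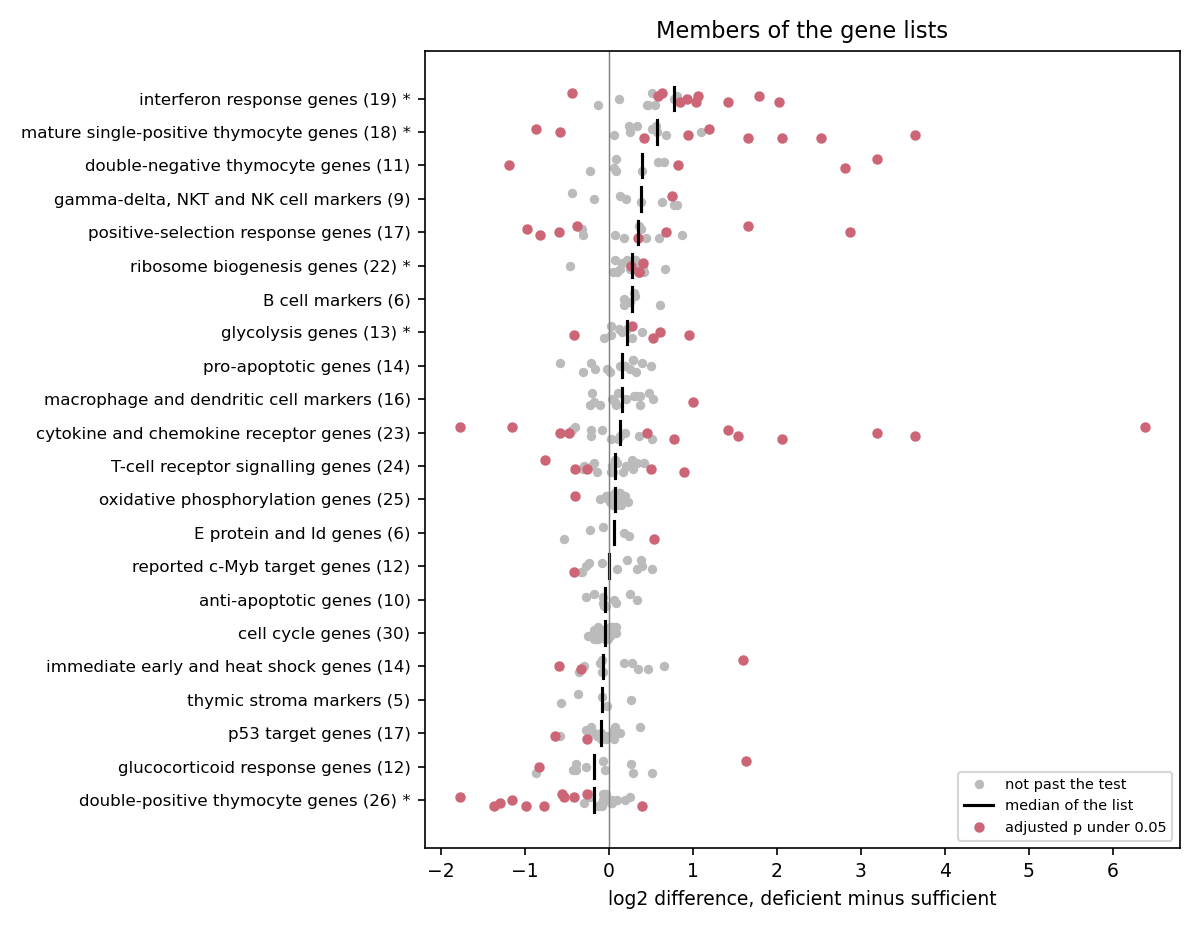
Log2 difference (deficient minus sufficient, as labelled) of each tested member of the 22 lists tested with camera, with the number tested in brackets. Red points passed an adjusted p of 0.05, grey points did not, black bars are list medians and asterisks mark the 5 lists past camera's threshold, 0 of which passed with an estimated correlation. Interferon response genes have the highest median, 0.78, and double-positive thymocyte genes the lowest, -0.172. Glucocorticoid response genes, which did not pass camera, have nearly the same median, -0.171.

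Genes of cell death and division did not pass as groups. Bcl2l1, the survival gene that encodes Bcl-xL, read 1043 ± 119 and 860 ± 98.7 on its brightest probe set 1420888_at (log2 -0.27 ± 0.11, adjusted p = 0.149), and -0.39 and -0.52 on its other probe sets past the filter. Of 10 anti-apoptotic and 14 pro-apoptotic genes, 0 passed over all genes and 0 adjusted over the list alone (camera adjusted p = 0.631 and 0.497). Camera placed the anti-apoptotic list downward, with a median of -0.04 and a mean of 0.008. The brightest tested members differed by -0.07 for Mcl1 and 0.29 for Bcl2l11, whose 4 other probe sets ranged from -0.51 to 0.10. Of 17 p53 target genes 2 fell, also 2 adjusted over the list alone: Gadd45a fell by 0.64 and Trp53inp1 fell by 0.26, with -1.16 on its other probe set (camera adjusted p = 0.149). Among 30 cell cycle genes 0 passed either way (camera adjusted p = 0.266), and Pcna differed by -0.01. Of 12 reported c-Myb target genes, 1 fell, Rag2, which was also the 1 call adjusted over the list alone (camera adjusted p = 0.497, downward, against a median of 0.007 and a mean of 0.026). Gata3 differed by -0.32 (adjusted p = 0.149). Of 25 oxidative phosphorylation genes 1 passed, as Cox7c fell by 0.40, and 0 adjusted over the list alone (camera adjusted p = 0.205).

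Signalling and receptor genes moved in both directions. Of 23 cytokine and chemokine receptor genes 8 rose and 4 fell (10 and 6 adjusted over the list alone; camera adjusted p = 0.191), the rises led by Il18r1 and Ccr7. Of 24 T-cell receptor signalling genes 2 rose and 3 fell (3 and 4 adjusted over the list alone; camera adjusted p = 0.775). The adhesion gene Cd2 rose by 0.89 ± 0.14 and the calcium-regulated factor Nfatc3 fell by 0.76 ± 0.16. Of 6 E protein and Id genes 1 rose, Tcf4 by 0.54, also 1 adjusted over the list alone (camera adjusted p = 0.915, downward, against a median of 0.06). Glucocorticoid response genes had 1 rise and 1 fall among 12 (1 and 3 adjusted over the list alone; camera adjusted p = 0.497): the kinase gene Sgk1 rose by 1.64 and the receptor gene Nr3c1 fell by 0.83, with its 4 other probe sets from -1.80 to -0.78 (-0.26 with the Xist level in the model, adjusted p = 0.813). Of 14 immediate early and heat shock genes 1 rose and 2 fell (3 and 3 adjusted over the list alone), with a median of -0.07, a mean of 0.12 and a camera adjusted p of 0.921. Jun rose by 1.60 (1.0 on its other probe set) and Egr1 fell by 0.60.

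Few markers of other cell types passed the test. Of 9 tested gamma-delta, NKT and NK cell markers 1 rose, the granzyme gene Gzma by 0.75 (2154 ± 209 to 3652 ± 484), also 1 adjusted over the list alone (camera adjusted p = 0.205). Of 6 B cell markers 0 passed either way, and Ighm differed by 0.18, with other probe sets at -0.19 and 0.39. As a list the B cell markers did not pass camera (adjusted p = 0.149) but passed fry, upward (adjusted p = 0.0158). Among 16 macrophage and dendritic cell markers the cathepsin gene Ctss rose by 1.0, with 0 calls adjusted over the list alone (camera adjusted p = 0.576). Of 5 thymic stroma markers 0 passed either way (camera adjusted p = 0.314), and Pecam1 differed by -0.36. Only 2 erythroid markers could be tested. Car2, a carbonic anhydrase gene, rose by 2.27 (217 ± 76.8 to 1069 ± 204), while the globin gene Hba-a2 differed by -0.12 (adjusted p = 0.665). The 1 granulocyte marker that could be tested, S100a8, differed by 0.65 (adjusted p = 0.176). As S100a8 was the only tested member, adjusting over its list leaves the unadjusted limma p of 0.0404. S100a8 was dim on 3 of 4 sufficient arrays and on 1 deficient array. Of the sex-linked list 1 gene, Xist, could be tested, and it rose by 5.09 ± 1.22 (adjusted p = 0.0236). Of the 40 named genes that changed, Fosl2 could not be tested in the 4 fits without a deficient array, where the dim filter removed it, and 9 lost the call when at least 1 array was left out: Cox7c (7 of 8 fits, adjusted p up to 0.0992), Xist (6, up to 0.0775), Ctss (5, up to 0.130), Mybbp1a (5, up to 0.0818), Nr3c1 (5, up to 0.102), Rsad2 (5, up to 0.0668), Trp53inp1 (4, up to 0.0954), Egr1 (3, up to 0.0703) and Rrs1 (2, up to 0.134). With the Xist level in the model, where sufficient replicate 1 alone carries the group term, 3 of the 40 differences (Trp53inp1, Nr3c1 and Xist itself) became over 1.5 times smaller. Others grew, as Egr1 went from -0.60 to -0.94 and Ctss from 1.0 to 1.56.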

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

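The Xist covariate, the position of sufficient replicate 1 and the use of the fit without deficient replicate 4 and of the Myb difference as tests of an explanation were chosen after the data were seen, while that fit, the Myb difference, the other splits and the search for single arrays were planned.

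In 5 of the 120 groups of 4 arrays examined, 1 array lay far from the other 3, and chance alone gives about 1 in 20. Xist, the noncoding RNA of the inactive X chromosome, read 4358.5 in sufficient replicate 1 and 23.4 to 36.7 in the other sufficient mice. The Y-linked genes ran the other way in that mouse: Eif2s3y read 2.1 against 1217 to 1335, Kdm5d 7.2 against 551 to 914, and Uty 9.5 against 202 to 250.5. Cd2 read 820.0 in deficient replicate 3 and 1176 to 1194 in the other deficient mice. Outside the genes analysed, 135 of the 3504 probe sets with no gene symbol or several symbols passed the threshold, led by 1418301_at with a log2 difference of 3.83 (adjusted p = 0.000326).

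The 992 changed genes went together with a difference in Xist level. Of the 35 splits of the 8 arrays into 4 and 4, 1, the real one, called as many genes, and the highest of the others called 8. A chance division would rank first in 1 of 35 cases, so it is unlikely but not excluded. The other splits carry the difference between the groups in their spread, which lowers their counts. The ranking does not tell what sets the groups apart. Without deficient replicate 4, with its high 18S signal, 1198 genes were called, which argues against that RNA as the source of the count. With the Xist level in the model the group term rests on sufficient replicate 1 alone. All 992 differences kept their sign there, which for the 931 whose groups do not overlap could not be otherwise. Their median size was 0.89 of that before, with 174 over 1.5 times smaller (Nr3c1 from -0.83 to -0.26) and 10 over 1.5 times larger. Il18r1 differed by 5.88, Fosl2 by 5.10, Maf by 5.01, Slamf6 by -1.13, Lig4 by -1.62 and Scn4b by -3.36. The median SE went from 0.128 to 0.206. All 992 genes were called with that array in the sufficient group, so their sign and size do not test an effect of sex. Sufficient replicate 1 lay at a median position of 0.229 between the other sufficient arrays (0) and the deficient arrays (1). It is the 1 sufficient array with high Xist and carries the group term of that fit. Sex and the labelled c-Myb status therefore cannot be told apart for the 992 genes, and either may contribute.

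Myb itself was not lower on the arrays labelled deficient, and the source names give the group labelled sufficient the conditional homozygous genotype. If the labels were exchanged, a fall of Myb transcript of at least 2-fold in the truly deleted group could show as a rise in the group labelled deficient. The brightest Myb probe set differed by 0.277, under either 2-fold bound, so exchanged labels cannot be told apart from a deletion that leaves these probes' target in place. What keeps this open is the unknown position of the probes relative to the deleted part. No array stood out of its own group toward the other in a way that a single swapped pair would need, as the median positions lay between -0.14 and 0.237 for sufficient and between 0.619 and 1.24 for deficient arrays.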

How the results depend on the processing

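The alternatives were fixed in advance, except the Xist covariate, which was chosen after the data were seen. Array weights gave 1742 changed genes (1033 higher, 709 lower), the Xist covariate 26 (15 and 11), an adjusted p under 0.01 gave 371 (211 and 160), and a change of at least 1.5-fold gave 518 (322 and 196). The last pair are stricter thresholds by construction, and for array weights the cause was not tested. The Xist covariate raised the median SE and left the 992 differences, taken there against sufficient replicate 1 alone, at a median of 0.89 of their size. Leaving out 1 array gave 494 to 1198 changed, 280 to 687 higher and 212 to 511 lower genes, and 437 of the 992 were called in all 8 such fits, which have fewer samples. The count was lowest without sufficient replicate 3 (494) and deficient replicate 2 (515), then deficient replicates 3 (579) and 1 (605). All other settings stayed within 1.5 times of 992, from 728 with median centring to 1311 with all probe sets counted, and the 992 genes kept their sign wherever tested, except 1 with the mean of probe sets and 1 without probe sets prone to cross-hybridise. With an estimated correlation 0 of the 5 lists passed camera, although the double-positive list had an unadjusted p of 0.0189. Fry called 7, these 5 and the lists of double-negative thymocyte genes and B cell markers. Lists of double-positive, mature, ribosome biogenesis and interferon genes passed camera in 21 of 21 refits, and glycolysis in 12. Of the lists not called in the main fit, cell cycle genes passed in 2 refits (lowest adjusted p = 0.0106) and double-negative genes in 2. Oxidative phosphorylation genes and macrophage and dendritic cell markers passed in 1 each. The Myb difference passed the threshold with array weights (0.337, adjusted p = 0.0116) and with the replicate number as a block (0.277, adjusted p = 0.0292). With 1 array left out it ranged from 0.223 to 0.329, passing without sufficient replicate 1 or 2 (adjusted p = 0.0448 and 0.0388) or deficient replicate 4 (0.0487). It was smaller with quantile normalization (0.18, adjusted p = 0.259) and without probe sets prone to cross-hybridise (0.042, adjusted p = 0.796). With the Xist level in the model it was 0.119. Deviations of same-numbered arrays from their group means correlated at 0.003, 0.172, -0.274 and 0.36. Replicate 4 of the sufficient group, but not every array, correlated best with its own number. These 4 values do not show whether the numbers pair the mice, which stays unknown. With the replicate block 1036 genes were called (619 higher, 417 lower), and the median SE was 0.122 against 0.128 without it. Dim signals limit the rest: without the dim filter 743 of 18193 genes were called.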

Other observations

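The genes in this part were chosen after their values were seen, as were both tests. Some further receptor genes rose along with Il18r1, while in the fixed list of cytokine and chemokine receptors, which did not pass as a group, 4 of 23 fell, among them Il10ra (log2 -1.15 ± 0.26) and Il17ra (log2 -0.47 ± 0.08), a chain of interleukin-17 receptors. Il18rap, the partner chain of the interleukin-18 receptor, rose from 15.4 ± 15.0 to 216 ± 108 (SD, n = 4; log2 2.88 ± 0.36, adjusted p = 0.000892). Il17re rose from 149.9 ± 49.98 to 712 ± 220 (log2 2.14 ± 0.24) and Il17rc, below the dim limit on all sufficient arrays, was at least 2.15-fold higher on deficient ones (6.25 ± 3.55 and 82.1 ± 51.3, adjusted p = 0.00266). Traf1, an adaptor of TNF receptors, rose by 1.98 ± 0.28 and the kinase gene Map3k8 by 2.09 ± 0.23. Tnfaip3 and Nfkbia, which encode inhibitors of NF-kappaB signalling, fell, Tnfaip3 from 2034 ± 364 to 745 ± 208 (log2 -1.45 ± 0.20) and Nfkbia by 0.37 ± 0.07. Lig4, the ligase that closes broken DNA ends in receptor gene rearrangement, fell from 1864 ± 194 to 543 ± 132 (log2 -1.78 ± 0.16, adjusted p = 0.000153). Gpr183, an oxysterol receptor, was likewise at least 5.74-fold higher (adjusted p = 0.000269), and Btla, an inhibitory receptor, rose by 2.07 ± 0.32.

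A pattern to follow up is the set of 35 genes other than Xist that were at least 4-fold higher on deficient arrays by the fitted difference (4 of them dim on all sufficient arrays), some of which varied widely between mice: Cd163l1 read 890.9 in deficient replicate 3 and 42.9 in deficient replicate 4, and 5830411N06Rik 4801 and 409.5. A single admixed cell type as the only source would give each gene a similar ratio between these mice, in the signal it adds. Without those 2 genes, which prompted the test, the log2 signal ratio had an SD of 0.613 over 33 genes. In 10000 lists of unchanged genes of like brightness the median was 0.406 and the highest 0.745, and 0.613 lay above 99.2% of them. That ratio includes signal already present on sufficient arrays, which differed between genes (mean 359 for Cd53 and 5.75 for Fosl2). Such differences can spread the ratio under admixture too. Taken above the sufficient mean the SD was 0.73, with no matched lists to compare. It is also 1 pair of mice, picked from those 2 genes, and deficient replicate 4 had the high rRNA control. The ratios therefore do not decide on a single admixed cell type. For mature gamma-delta T cells as the only source, the 7 measurable of 16 markers had a median log2 difference of 0.242 and an upper quartile of 0.738. Both lay below the smallest change of the set, 2.02. The brighter ones without a receptor gene, Tmem176b (319 to 333) and Tmem176a (136 to 157), and Cd44 (135 to 113) already had signal on sufficient arrays. An admixed share would raise such genes by a smaller fold than genes near the background, so the markers do not decide on this source. In addition, 8 of the 16 stand in another list, and the anti-CD4 column would remove most cells without CD4. Since Trgv4 rose from 280 ± 96.8 to 761 ± 289 (log2 1.38, adjusted p = 0.0106) and Trgv1 read 264 ± 110 and 520 ± 199 (adjusted p = 0.0627), a small share of gamma-delta lineage cells may add to part of the set, and sex, which differs nearly in step with the groups, stays open for all of it.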
